A study of Mus musculus with 2 samples.

How the data were processed

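RNA was taken from MIN6 cells at each glucose concentration, and 1 library per concentration was analysed. Whether a library came from a single culture or a pool is not given in the sources used here. The labels name total RNA and Trizol extraction. The library kit, poly(A) selection or ribosomal depletion, strandedness and read length are not given in the sources used here. The deposited values are FPKM, fragment counts scaled to gene length and library size, per the file headers, 1 per gene and library. HISAT2 and Cuffdiff and the genome build GRCm38 are named in the submitters' processing notes, without versions or settings, and the annotation release is not given in the sources used here. FPKM divides by gene length and by library size, so a value depends on how reads were divided among isoforms and near-identical genes, and short genes are poorly estimated. An exact 0 can be a failed estimate: such genes are described only as listed at 0. Of the rows, 1 was empty and was not used.

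Both libraries were mapped to a group from the treatment label, with 1 sample per group. The main choices, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. With 1 library per group no test, SE or p-value was possible. The log2 change was log2((FPKM at 25 mM + 1)/(FPKM at 2.8 mM + 1)), with a pseudocount of 1, and genes with a mean FPKM of at least 1 over both libraries counted as expressed. Genes at least 2-fold apart were counted in each direction. For 33 gene lists, 30 of which had at least 3 expressed members, the median log2 change was taken with a binomial (order statistic) interval over members, of at least 95% coverage except for the 4 members of the endothelial and immune list (87.5%). Its percentile was found among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. Members at least 1.5-fold apart were counted. Genes occur in more than 1 list, such as Per1 and Nfil3 among immediate early and clock genes.

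Genes were named by rule. They were the 10 highest and 10 lowest log2 changes among genes with a mean FPKM of at least 5, leaving out unnamed gene models, pseudogenes, small RNAs by symbol prefix and genes without a symbol. Added to these were at most 2 highest and 2 lowest expressed members of each list, genes fixed beforehand (Ins1, Ins2, Iapp, Pdx1, Mafa, Slc2a2, Txnip, Fos, Egr1 and Junb, and 1 that is not reported here) and the 5 most abundant genes. Gcg, Sst, Ppy, Rmrp, Rnu3a, mt-Rnr1 and mt-Rnr2 were named after their values were seen.

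Gene coordinates, transcript lengths and GC content came from GENCODE release 21 for mouse (GRCm38), which held 99.4% of the gene identifiers. Reads that a gene would share with a copy were estimated as the percentage of the 31-mers of its longest transcript found in transcripts of other genes. Where a shorter transcript is the one copied, this percentage can understate the sharing. Copies outside the annotation were not analysed here. The FPKM of low genes with 1 transcript of at least 800 nt fell on steps, from which total fragments and fragment length were fitted. This gave 19660000 fragments of 290 nt for the 2.8 mM library, with 94.8% of 2560 values within 0.1 of a whole fragment, and 16760000 of 270 nt for the 25 mM library, with 94.0% of 2331. For single-transcript genes of at least 500 nt, exact Clopper-Pearson 95% intervals were computed from the recovered fragments. They cover counting error only and compare the libraries, not the conditions. They do not hold for genes that share most of their 31-mers with another gene.

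The steps were tested on simulated data with known changes for 55466 genes. All changes of 3-fold and 4-fold (100% of each) in 200 altered genes were found at 2-fold or more in the right direction. The altered genes had a mean FPKM of at least 5 and a longest transcript of at least 800 nt. Short genes were not altered and copies were not simulated, so this recovery does not cover them. A list lowered by a log2 change of 0.2 was at percentile 0 and an unaltered list at 34.8. Only counting error separated the simulated libraries, with the same fragment length in both. The deposited libraries differed by more than counting error, so these percentiles do not carry over to them. Alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5, thresholds of 1.5-fold and 3-fold, 3 rescalings, leaving out unnamed gene models, summing rows with 1 symbol, and random lists without matching. Alternatives chosen after the data were seen were the restriction to long genes without a copy, to genes with 1 transcript, and removal of a linear trend on GC content, transcript length and expression. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.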

Results

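The transcriptome of MIN6 cells was measured by RNA sequencing at 2 glucose concentrations. MIN6 is a mouse insulinoma line that makes and secretes insulin and is used as a model of the pancreatic beta cell. Cells were held at 2.8 mM glucose for 0.5 h and then kept for 1 h at either 2.8 mM, a low level, or 25 mM, a level above that needed to trigger insulin secretion, in a bicarbonate-buffered salt solution. There was 1 library per concentration, so no value below has a replicate error, no difference was tested against the spread between replicates, and every difference is one between 2 libraries. Each library listed 55466 genes in FPKM. FPKM was above 0 for 20068 genes at 2.8 mM and 19412 genes at 25 mM, and 12694 genes had a mean of at least 1. The steps between low values corresponded to 19660000 fragments in the 2.8 mM library and 16760000 in the 25 mM library.

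Both libraries had the profile of an insulin-producing cell. Ins2, the main mouse insulin gene (ENSMUSG00000000215, GRCm38 chromosome 7, 142678656 to 142743381), was the most abundant transcript at 60328 FPKM at 2.8 mM and 50846 FPKM at 25 mM, which was 8.59% and 7.59% of the summed FPKM. By mean FPKM over both libraries it was followed by the neuropeptide Y gene Npy (13303 and 11314 FPKM), the islet amyloid polypeptide gene Iapp (8637 and 8198 FPKM), mt-Co1 (8651 and 8133 FPKM) and the granule protein gene Scg2 (5001 and 4938 FPKM). Ins1 stood at 4194 and 4344 FPKM. The beta-cell transcription factor genes Pdx1 and Mafa were at 92.7 and 88.0 FPKM and at 77.1 and 87.0 FPKM. Slc2a2, the glucose transporter of rodent beta cells, was at 0.469 and 0.653 FPKM.

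Transcripts of other islet and pancreatic cell types were compared in the same way. Gcg, which encodes glucagon, was at 2804 FPKM at 2.8 mM and 2764 FPKM at 25 mM, whereas Sst and Ppy were listed at 0 in both libraries. Of 27 acinar markers, 2 were expressed (Cela1 and Bhlha15), of 18 stromal markers 1 (Tagln), and of the 5 listed erythroid markers 0. The 7 expressed endocrine markers had a median log2 change of 0.02, the 6 ductal markers -0.07 and the 4 endothelial and leukocyte markers 0.09, each within the range of random lists. Among genes normally kept low in beta cells, Ldha, for lactate dehydrogenase A, was at 887 and 827 FPKM, and the 7 expressed members had a median log2 change of -0.03.

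The comparison asked how the transcriptome differs after 1 h at 25 mM glucose from that after 1 h at 2.8 mM. Most transcripts were at similar levels. Of the 12694 expressed genes, 95.5% differed by less than 1.5-fold, and the median log2 change was -0.02. The glucose-sensitive gene Txnip, which encodes thioredoxin-interacting protein, was at 23.3 FPKM at 2.8 mM and 27.8 FPKM at 25 mM (log2 change 0.25), and Ins2 was lower at 25 mM by a log2 change of -0.25. In contrast, immediate early genes, which are transcribed within minutes of a stimulus, were lower at 25 mM as a group, with 33 of 38 expressed members below their level at 2.8 mM. Changes are given as log2((FPKM at 25 mM + 1)/(FPKM at 2.8 mM + 1)), which understates the change of low genes. Across genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) between the libraries was 0.973.

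**Figure D1:**
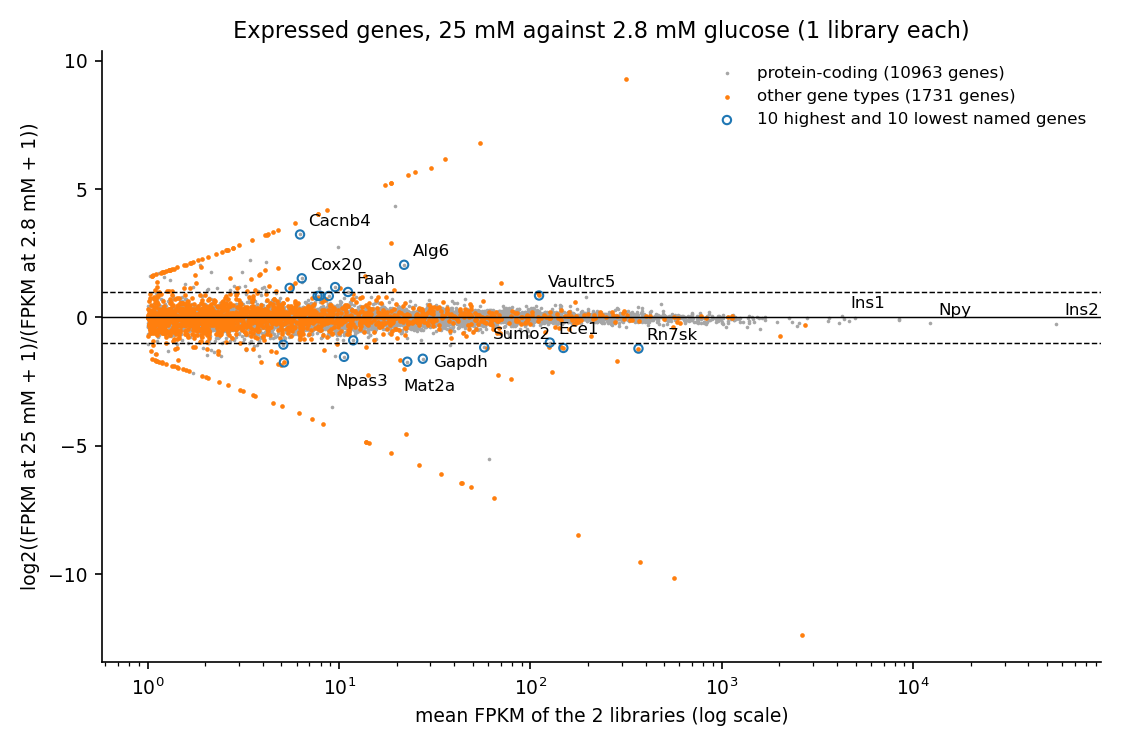
Log2 change between the library at 25 mM and the library at 2.8 mM glucose (vertical axis) against the mean FPKM of both (horizontal axis, log scale) for the 12694 expressed genes, with dashed lines at 2-fold. Grey points are protein-coding genes, orange points are other gene types, and most points far beyond the dashed lines are orange; circles mark the 10 highest and 10 lowest named genes.

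At least 2-fold differences were found for 219 genes, 113 higher and 106 lower at 25 mM. The counts were 172 and 189 with a pseudocount of 0.1, 37 and 45 with a pseudocount of 5, 30 and 44 with a mean FPKM of at least 5, 25 and 24 among named genes only, and 199 and 181 after rescaling without mitochondrial and top 10 genes. Protein-coding genes made up 32 of the genes that were higher and 28 of those that were lower. The rest included 103 pseudogenes, of which 95 were processed pseudogenes, and 30 small or structured non-coding RNAs. With genes restricted to those with a transcript of at least 300 nt and under 20% of their 31-mers shared with another gene, a restriction chosen after the data were seen, 30 genes were higher and 26 lower. In a simulation in which only counting error separated the libraries, 61 of 12479 unchanged genes differed by at least 2-fold. There, genes about as long as a fragment or shorter were all given the same arbitrary length for scaling. Copies and isoforms were not simulated, so that count is no baseline for the 219.

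Among the genes of the 2 sets of 10 chosen by rule, the highest log2 change was that of Cacnb4, which encodes a beta subunit of voltage-gated calcium channels (ENSMUSG00000017412, chromosome 2, 52428320 to 52676831). It was at 0.394 FPKM at 2.8 mM and 12.1 FPKM at 25 mM, a log2 change of 3.23. Alg6, a glucosyltransferase gene of N-glycan assembly (ENSMUSG00000073792, chromosome 4, 99715664 to 99763460), was at 7.88 and 35.8 FPKM, a log2 change of 2.05. Cox20, a gene for an assembly factor of cytochrome c oxidase, was at 2.81 and 9.96 FPKM, and Tbl1xr1, for a subunit of a transcriptional corepressor complex, at 5.44 and 13.6 FPKM. Faah, which encodes fatty acid amide hydrolase, was at 7.11 and 15.1 FPKM, and Cacna1d, for the L-type calcium channel subunit Cav1.3, at 5.26 and 10.2 FPKM. Halr1, a long non-coding RNA, Vaultrc5, a vault RNA, Lrch4 and Coro1b completed the 10 highest, with log2 changes of 1.15, 0.86, 0.85 and 0.84. Vaultrc5, at 143 nt, is shorter than the fitted fragments, so its FPKM is poorly estimated. Lrch4 shared 98.2% of its 31-mers with other annotated transcripts, so its reads could not be assigned to it alone.

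At the other end, Mat2a, which encodes the methionine adenosyltransferase that makes S-adenosylmethionine (ENSMUSG00000053907, chromosome 6, 72432799 to 72439558), was at 35.4 FPKM at 2.8 mM and 10.0 FPKM at 25 mM, a log2 change of -1.72. The neuronal transcription factor gene Npas3 was at 16.3 and 4.96 FPKM and Ece1, for endothelin-converting enzyme, at 168 and 84.7 FPKM. Bach2os, a long non-coding RNA, had the lowest log2 change of these sets at -1.75, and Kank3 and Crip1 had log2 changes of -1.06 and -0.89. Gapdh (41.7 and 13.0 FPKM) and Sumo2 (79.7 and 34.9 FPKM) were also among the 10 lowest, but shared 30.7% and 34.6% of their 31-mers with other annotated genes. Also among them were 2 abundant non-coding RNAs transcribed by RNA polymerase III, Rn7sk (513 and 221 FPKM) and Rn7s2 (207 and 90.3 FPKM). They shared 72.8% and 100% of their 31-mers with other annotated genes. At 331 and 300 nt they are little longer than the fitted fragments, so their FPKM is also poorly estimated.

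Immediate early genes had a median log2 change of -0.13 over 38 expressed members (95% binomial interval -0.29 to -0.08), at percentile 0.58 among random lists matched on expression. Of these, 3 were at least 1.5-fold lower and 0 at least 1.5-fold higher. The lowest were Maff, a small basic leucine zipper factor gene (20.3 and 10.9 FPKM, log2 change -0.84), and Sik1, a salt-inducible kinase gene (2.33 and 0.980 FPKM, -0.75). Egr1 was at 16.9 and 11.5 FPKM, Fos at 7.24 and 5.09 FPKM and Junb at 20.6 and 15.6 FPKM. Csrnp1 (1.13 and 1.65 FPKM) and Ier5 (8.53 and 9.47 FPKM) were higher at 25 mM.

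**Figure D2:**
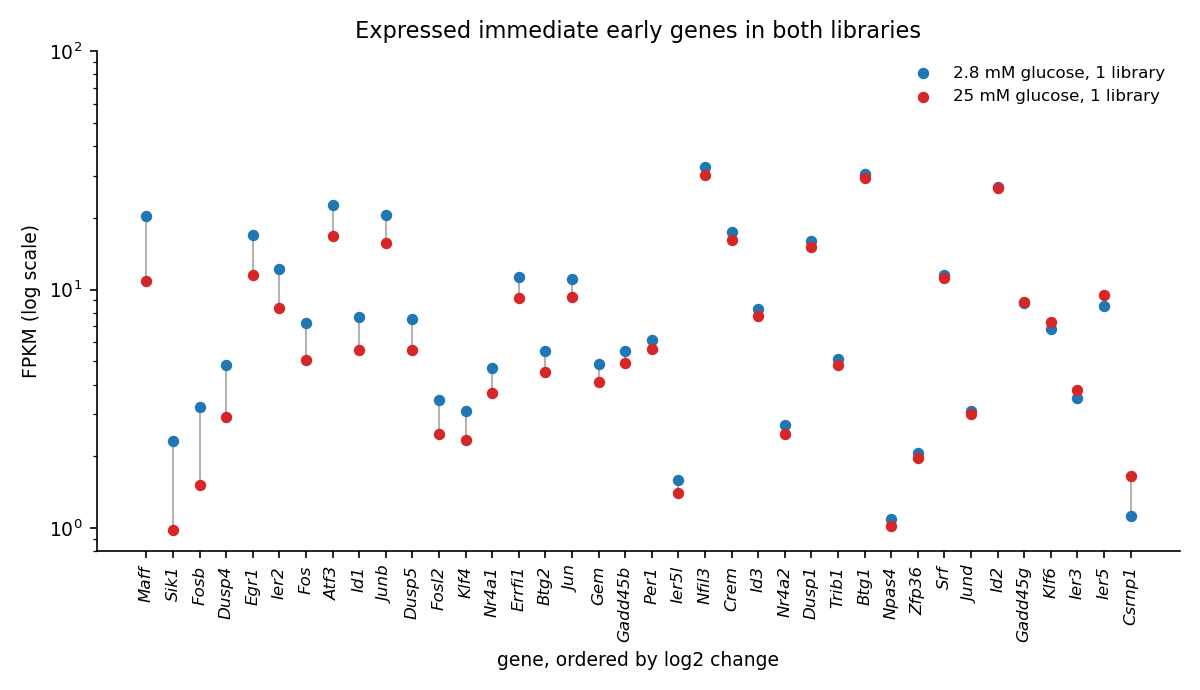
FPKM (log scale) of the 38 expressed immediate early genes in the library at 2.8 mM (blue) and the library at 25 mM glucose (red), ordered by log2 change; grey lines join the values of a gene. The red point lies below the blue one for 33 genes, and the gap is widest for genes at the left such as Maff (20.3 and 10.9 FPKM).

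Among the 30 lists with at least 3 expressed members, 6 had medians outside the central 95% of random lists, and these 6 were all low. The 13 protein-coding genes of the mitochondrial genome had a median log2 change of -0.18 (interval -0.38 to -0.01, percentile 0), from mt-Nd5 (1821 and 1329 FPKM, -0.45) to mt-Atp6 (85.0 and 91.7 FPKM, 0.11). The reads of mt-Atp6 and mt-Co3 could not be assigned to them alone, since 99.5% and 99.9% of their 31-mers occur in other annotated genes. For the abundant mt-Co1 the share was 63.9%. Among long genes without a copy the mitochondrial median was -0.23. Ribosomal protein genes had a median of -0.08 over 84 members (interval -0.09 to -0.05, percentile 0). Of these, 2 were at least 1.5-fold lower, Rpl21 (6.01 and 3.04 FPKM) and the pseudogene Rpl32l. They shared 27.4% and 52.6% of their 31-mers with other annotated genes. Rps15a, at 397 and 567 FPKM, was the highest member.

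Targets of the hypoxia-inducible factors had a median of -0.10 over 19 members (interval -0.20 to 0.07, percentile 2.11), with the pyruvate dehydrogenase kinase gene Pdk1 at 15.1 and 9.22 FPKM and the mitophagy receptor gene Bnip3 at 102 and 73.7 FPKM. Hilpda, a lipid droplet protein gene of the same list, was at 3.08 and 3.68 FPKM. Clock genes had a median of -0.11 over 18 members (interval -0.18 to 0.01, percentile 2.26). Per2 was at 6.52 and 5.01 FPKM, and Arntl, which encodes the clock activator BMAL1, at 9.61 and 10.6 FPKM. Replication-dependent histone genes had a median of -0.15 over 23 members (interval -0.29 to 0.06, percentile 0.78), which became 0.07 when short genes and genes with a copy were left out. With both libraries rescaled to the same sum, which moved the median of expressed genes to 0.045, the medians were -0.11 for mitochondrial, -0.0075 for ribosomal protein, -0.033 for hypoxia, -0.049 for clock, -0.077 for histone and -0.080 for immediate early genes. Among long genes without a copy the hypoxia median was -0.039, and with random lists not matched on expression the hypoxia and clock lists were at percentiles 3.55 and 2.60, inside the central 95%.

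**Figure D3:**
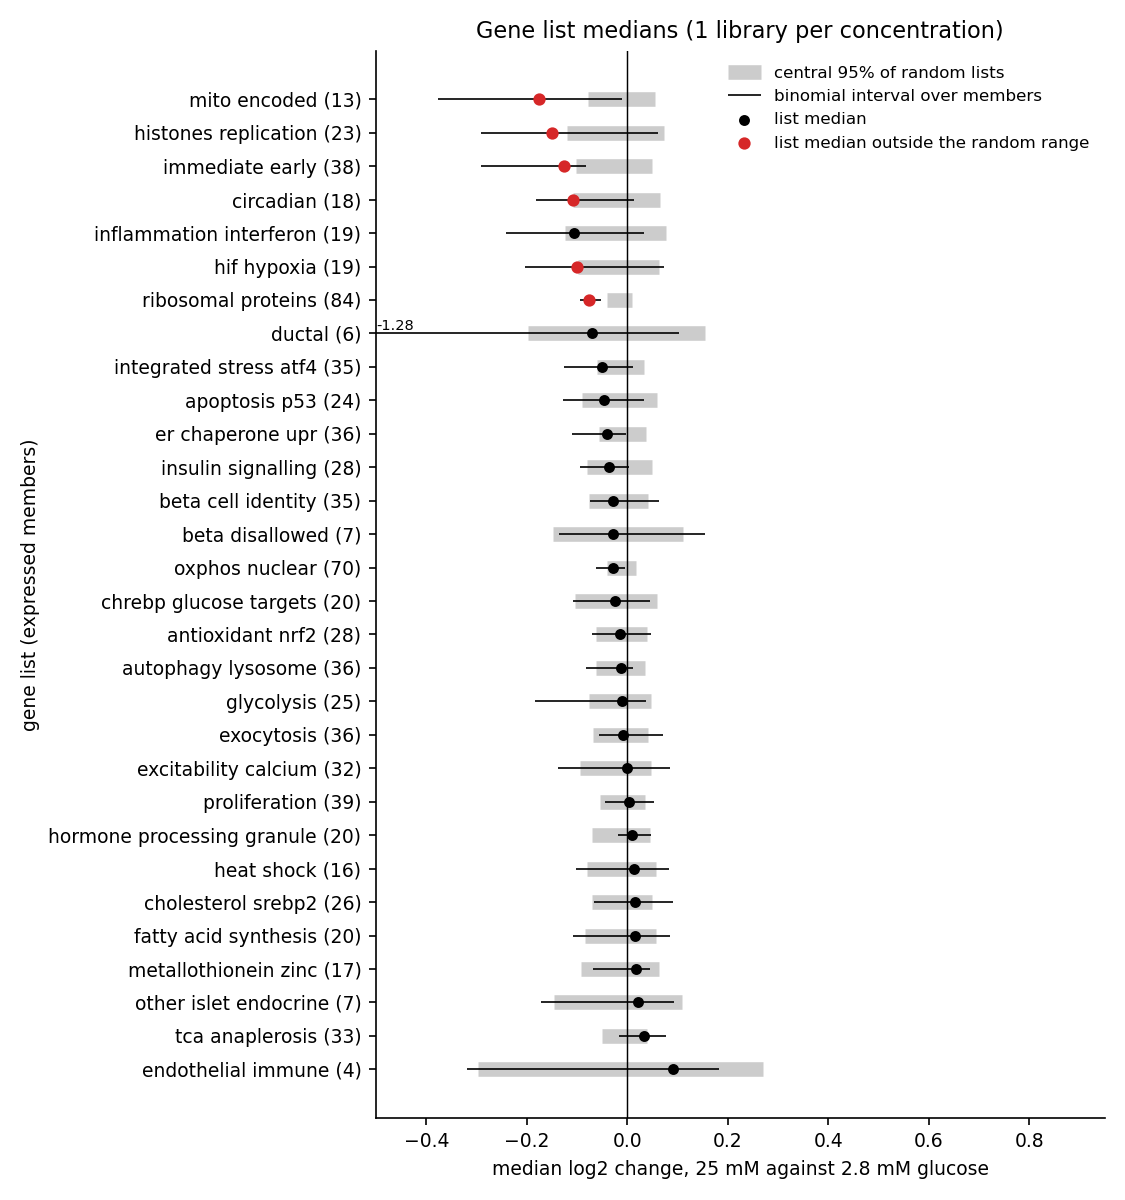
Median log2 change between 25 mM and 2.8 mM glucose (horizontal axis) of the 30 gene lists with at least 3 expressed members (vertical axis, members in brackets). Thin lines are binomial intervals over members with a coverage of at least 95%, except for the endothelial and immune list, whose 4 members allow 87.5%. Grey bars are the central 95% of matched random lists, and the 6 red medians lie below that range; the ductal interval extends to -1.28, beyond the axis.

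Metabolic and secretory lists lay within the range of random lists. Targets of the carbohydrate response factor ChREBP had a median log2 change of -0.02 over 20 members, although Pklr, for liver-type pyruvate kinase, was at 8.14 and 4.17 FPKM (-0.82) and Arrdc4 at 4.20 and 3.32 FPKM. Beta-cell identity genes had a median of -0.03 over 35 members, hormone processing and granule genes 0.01 over 20, exocytosis genes -0.01 over 36 and ion channel and calcium genes 0.00 over 32. In the last list, Cacna1d was the only member at least 1.5-fold apart. Vgf, a granin-family gene, was at 154 and 194 FPKM. Glycolysis had a median of -0.01 over 25 expressed rows, of which 4 were at least 1.5-fold lower, Gapdh among them. Another of the 4 was a minor Aldoa row (2.41 and 1.14 FPKM), whereas the main Aldoa row was at 439 and 472 FPKM. The tricarboxylic acid cycle list had the highest median among the metabolic lists at 0.03 over 33 members (percentile 94.9), from Suclg2 at 66.4 and 45.1 FPKM (-0.55) to Sdhc at 41.0 and 52.5 FPKM (0.35). Cholesterol synthesis genes were at 0.02 over 26 members, with Fdps at 115 and 144 FPKM, and fatty acid synthesis genes at 0.02 over 20. Nuclear respiratory chain genes were at -0.03 over 70 members.

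Stress and growth lists also lay within that range. The median log2 change was -0.04 for endoplasmic reticulum chaperones, -0.05 for ATF4 targets, 0.01 for heat shock genes and -0.02 for antioxidant genes. It was 0.02 for metallothioneins and zinc transporters, 0.00 for DNA replication and mitosis, -0.05 for p53 and BCL2 family genes, -0.11 for inflammatory genes, -0.04 for insulin signalling and -0.01 for autophagy and lysosome genes. Single members stood apart from their lists. Kif11, a mitotic kinesin gene, was at 0.898 and 7.45 FPKM, Hspa4l, a heat shock protein gene, at 4.05 and 0.786 FPKM, and Ppargc1a, which encodes a coactivator of mitochondrial biogenesis, at 6.73 and 3.61 FPKM.

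For genes with a single transcript, the fragments behind a value could be recovered, and an exact interval for counting error alone could be given. On this scale, without a pseudocount, the interval of the log2 ratio was 0.03 to 0.07 for Ins1, -0.25 to -0.22 for Npy, 0.11 to 0.24 for Mafa and 0.18 to 0.67 for Cebpb. It included 0 for others, such as Ier5 (-0.03 to 0.33) and Bag3 (-0.005 to 0.47). Protein-coding genes with a mean FPKM of 10 to 30 differed between the libraries with a robust SD of 0.14 in log2 across genes. For the 192 single-transcript genes among them, each difference was divided by its own counting SD, and these ratios had a robust SD of 1.92, where counting error alone gives about 1.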

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

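The restriction to long genes without a copy, the restriction to 1 transcript and the removal of the GC and length trend were chosen after the data were seen. Against 113 genes at least 2-fold higher and 106 lower, the counts were 172 and 189 with a pseudocount of 0.1, 37 and 45 with a pseudocount of 5, and 30 and 44 with a mean FPKM of at least 5. They were 199 and 181 after rescaling without mitochondrial and top 10 genes, 25 and 24 among named genes only, 30 and 26 among long genes without a copy, 247 and 318 at 1.5-fold, and 73 and 61 at 3-fold. They were 160 and 161 without a filter. The threshold, filter and restriction settings change the number of genes that can pass by construction. A larger pseudocount shrinks every log2 change, so it also lowers the counts by construction. For the rescaling the cause was not tested. The median of expressed genes, -0.02, was 0.045 with both libraries rescaled to the same sum, 0.022 rescaled without mitochondrial and top 10 genes and 0.00 when centred, as centring fixes. Rescaling to the same sum moved list medians with it, to 0.077 for hormone processing, -0.080 for immediate early, 0.057 for glycolysis, 0.10 for the tricarboxylic acid cycle, 0.040 for nuclear respiratory chain and 0.028 for endoplasmic reticulum chaperone genes. It gave 0.016 for ATF4 targets, 0.089 for heat shock, 0.051 for antioxidant, 0.081 for zinc, 0.072 for replication and mitosis, -0.0075 for ribosomal protein, 0.031 for insulin signalling and 0.055 for autophagy genes. Rescaling without mitochondrial and top 10 genes gave 0.052 for hormone processing, 0.015 for nuclear respiratory chain, 0.0029 for endoplasmic reticulum chaperone, 0.058 for zinc, -0.032 for ribosomal protein, 0.0062 for insulin signalling and 0.031 for autophagy genes. These are shifts common to the genes of a library, and 13 and 11 lists changed sign under the 2 rescalings, none of them among the 6 low lists. Among long genes without a copy the histone median turned from -0.15 to 0.065 and the ribosomal protein median was -0.048; with the GC and length trend removed the latter was -0.11; the cause was not tested. All 18 named genes at least 2-fold apart kept their direction under the pseudocount, scaling and row-summing settings, but 9 were less than 2-fold apart under at least 1 of them: Ambp (-0.53), H3c10 (-0.48), H2bc18 (-0.58), Kank3 (-0.62), Hspa4l (-0.64), Halr1 (0.69), Tbl1xr1 (0.84), Cox20 (0.94) and Bach2os (-0.98). No paired analysis was possible because there was 1 library per concentration.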

Other observations

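All tests in this part were chosen after the data had been seen. Those of isoforms over all gene types and of GC content and length were set before their own values were computed; those of shared copies, short transcripts, isoforms among protein-coding genes, zinc finger genes and RNAs without a poly(A) tail were chosen after related values were seen. The zinc finger genes were picked after an unplanned scan of gene ontology terms on the same changes, so their value cannot count in favour of an explanation. Zinc finger protein genes (symbols Zfp and a number) had a median log2 change of -0.10 over 273 expressed members (interval -0.12 to -0.08), with 182 members lower and 91 higher at 25 mM. Non-coding RNAs without a poly(A) tail diverged: Rn7sk, Rn7s2 and Rmrp were lower at 25 mM with log2 changes of -1.21, -1.19 and -0.60. Vaultrc5 was higher at 0.86. At 143 nt it is shorter than the fitted fragments, and Rn7sk and Rn7s2, at 331 and 300 nt, are little longer than them. The FPKM of these 3 is therefore poorly estimated. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 were at 0.05 and 0.04. Of the genes for the U3 RNA, the rows for Rnu3a moved in opposite directions, 1 from 68.3 FPKM to 0.00181 FPKM and another from 0.0759 FPKM to 60.3 FPKM. The high value lay in a different row in each library, so these rows cannot be read as opposite changes of U3 RNA. Both rows were among the 11 RNAs without a poly(A) tail examined below.

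The first pattern was the set of genes at least 2-fold apart between the libraries. Of 218 such genes with an annotated length, 63.3% (exact binomial interval 56.5 to 69.7) shared at least 20% of their 31-mers with another gene, against 14.3% of the other expressed genes. Their longest transcript was under 300 nt in 46.3% (39.6 to 53.2), against 0.409%. Division of reads among near-identical copies and poor estimates for genes no longer than the fragments are therefore candidate explanations for much of this set. Among the 56 that were long and without a copy, 67.9% (54.0 to 79.7) had more than 1 transcript, below the 90.4% of other such genes. That comparison mixed gene types: among its 34 protein-coding genes the share was 91.2% (76.3 to 98.1), against 93.0% of other protein-coding genes, so isoform division stays open, as does an effect of glucose, which was not tested for want of replicates.

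The second pattern was the lower level of immediate early genes at 25 mM. After a linear trend on GC content, transcript length and expression was removed, the list stayed at percentile 0.18 of random lists. This argues against that linear trend as the whole cause. The trend explained only 0.52% of the variance among the 10950 genes fitted, and other forms of dependence were not tested. A lower level of all short-lived mRNAs was left undecided: zinc finger genes were at percentile 0, but that list was picked for its shift. Handling of the cells and an effect of glucose stay open and cannot be told apart with 1 library each.

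The third pattern was the lower level of mitochondrially encoded and ribosomal protein genes. With the same trend removed, the higher of both percentiles was 0.01, which argues only against a linear trend on GC content and length as the whole cause. That trend explained 0.52% of the variance among the genes fitted. Its removal moved the ribosomal protein median from -0.08 to -0.11 and the mitochondrial median from -0.18 to -0.17. Other forms of dependence on GC content and length were not tested. Carry-over of RNA without a poly(A) tail was examined through 11 expressed non-coding RNAs of that kind, whose median log2 change was -0.73 (interval -1.21 to 0.86). That test was void, because mRNAs of ribosomal proteins and most mitochondrial mRNAs carry a poly(A) tail, so the value says nothing on this pattern. Handling of the cells and an effect of glucose were not tested and stay open.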
